A study of Taeniopygia guttata with 134 samples.

How the data were processed

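RNA from 3 brain regions of individual male zebra finches was sequenced after selection of polyadenylated RNA and library preparation with the NEBNext Ultra kit, per the labels' protocols. The labels name the regions by the codes HY, NST (or NS) and TN, which were matched to the region names of the design text by their abbreviations. They code the control injection as S, whereas the design text writes C. Dose and time after injection are not given in the sources used here. Alignment used HISAT2 and counting used HTSeq 0.6.1, per the submitters' processing notes. The genome build and annotation are not given in the sources used here.

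The values deposited by the authors are whole-number read counts per gene, not normalized, for 18618 gene identifiers, as the values themselves show. All columns of the table matched a library by its label, and the table held no rows other than genes. Gene identifiers were looked up in a table of zebra finch genes (assembly bTaeGut7.mat), which matched 0 of 18618. Gene names, and the 32 gene lists and cell type markers fixed before the data were examined, could therefore not be used. The rule for named genes had asked for gene symbols. In its place, after the data were seen, the 2 largest mean rises and the 2 largest mean falls were taken among genes called in all 3 regions with a mean of at least 1 CPM in each. Whether the counting used strand is not known, and genes that overlap or have near-identical copies may share reads.

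Groups were formed by region, social setting and injection. The replicate number in the labels recurs across regions and was taken to mark a male, so that replicates of a group are separate males. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood model with trended dispersion and robust estimation was fitted to the 8 groups of each region. The effect of LPS was tested as the mean of the 4 settings, in each setting, and as a 3 degree of freedom interaction with setting. The effect of setting was tested among control males. All tests were 2-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. SE values of log2 changes were derived from the fitted change and its F statistic.

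Comparisons between regions were fitted to all libraries together with the male as a block. The pairing comes from the design, in which regions were dissected from the same males. As a check, deviations from group means were correlated between libraries of the same number, with a median r across genes of 0.539 for NST with HY, 0.479 for TN with HY and 0.509 for TN with NST. The correlation was over 0.1 for 42 of 45, 40 of 42 and 42 of 43 males. Males 32 and 33 and NST of male 19 were the exceptions and are described in the closing section. Among 2928 pairs of libraries of the same region, the lowest chi-square per gene was 9.40 (median 34.1), above what counting error alone gives, so no libraries were merged.

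Scores were computed from log2 CPM (prior count 2) and compared by exact permutation or by 100000 permutations. The score, which was added after NF had been seen to have the fewest calls, the comparisons over both injections, the tests within males with limma 3.58.1, and the parting of males into 2 sets were added after the data were seen. Each model was tested on simulated data with 200 changed genes. For the averaged LPS effect it recovered 96%, 92% and 92% of changes of 1 on the log2 scale in HY, NST and TN, with 4, 12 and 10 false calls among 186, 197 and 182. For the difference of the LPS effect between TN and HY with the block it recovered 90%, with 7 false calls among 179. The simulated libraries were drawn from a common mean per gene, without differences between males or between regions. The last value therefore does not show how the block performs on the real, paired libraries. Alternatives were scaling by DESeq2 size factors (RLE), no filter on low counts, DESeq2 1.42.0, 2 surrogate variables from sva 3.50.0, fits to only the groups compared, no block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With total counts of 7339290 or more per library, the spread between males, with a biological coefficient of variation of 0.277 in HY, 0.272 in NST and 0.306 in TN, rather than counting error limited the precision for all but low counts.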

Results

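Gene expression was measured by RNA sequencing in 3 brain regions of male zebra finches (Taeniopygia guttata), a songbird that forms lasting pairs. The males had received an injection of lipopolysaccharide (LPS), a component of bacterial cell walls that sets off an immune response, or a control injection. Afterwards males were alone (ISO), stayed with a female they knew (KFC), rejoined a female they knew (KF) or met an unfamiliar female (NF). The regions were the hypothalamus (HY), the bed nucleus of the stria terminalis (NST) and the nucleus taeniae (TN). The design addresses how the brain's response to an immune challenge depends on the social setting. There were 45 libraries from HY, 46 from NST and 43 from TN. Going by the numbers in the labels they came from 46 males, of which 42 contributed all 3 regions and 4 contributed 2.

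Each group held 4 to 6 libraries. In HY there were 6 LPS and 6 control males in ISO and KF, 5 and 5 in KFC, and 5 LPS and 6 control males in NF. In NST every group held 6 males except both KFC groups, which held 5. In TN there were 6 and 6 males in ISO and KF, 5 and 5 in KFC, and 4 LPS and 5 control males in NF. Total counts ran from 7339290 to 13159800 per library in HY (median 8794620), from 7902420 to 11879200 in NST (median 9340590) and from 9049820 to 14096500 in TN (median 11576000). Mean totals of LPS and control libraries did not differ detectably in HY (2-sided permutation p = 0.528), NST (permutation p = 0.720) or TN (permutation p = 0.522). TN had the highest median depth.

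**Figure D1:**
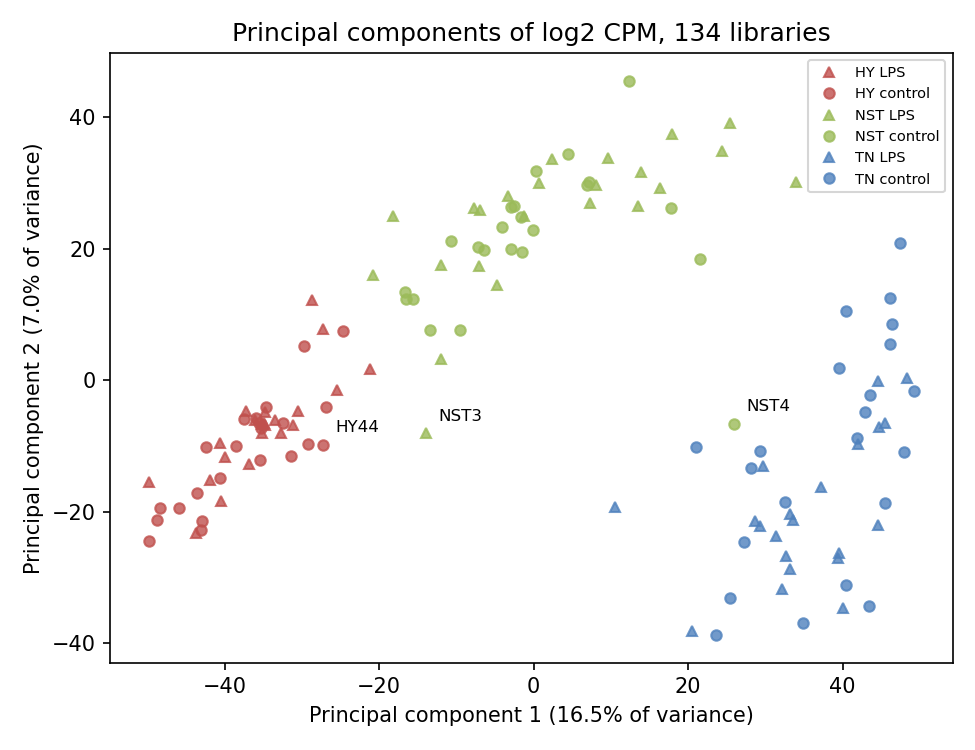
Principal components 1 and 2 of log2 CPM over 15097 genes, with 1 point per library, coloured by region (triangles LPS, circles control). Component 1 holds 16.5% of the variance and runs from HY (-49.8 to -21.2) through NST (-20.9 to 33.9) to TN (10.6 to 49.3), with NST and TN overlapping.

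The regions differed widely in control-injected males, which gives the background for the response to LPS. Within males, 9088 of 15097 genes differed between TN and HY, 4452 of them higher in TN and 4636 higher in HY. Between NST and HY 6680 genes differed, 3313 higher in NST and 3367 higher in HY. Between TN and NST 5894 genes differed, 2990 higher in TN and 2904 higher in NST. More than 2-fold differences were found for 1562, 626 and 665 of these genes, in the same order. Every library but 2 was closest to the median profile of its own region. NST replicate 3 (NF, LPS) correlated slightly more with the HY median (r = 0.973 across genes) than with the NST median (r = 0.972), and NST replicate 4 (NF, control) more with the TN median (r = 0.973) than with the NST median (r = 0.968). Genes are not independent replicates in these correlations.

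LPS changed the expression of many genes in each region when averaged over the 4 settings, and rises outnumbered falls. In HY 473 genes rose and 237 fell among 14420 tested. In NST 530 rose and 271 fell among 14386, and in TN 383 rose and 172 fell among 14598 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median rise was larger than the median fall. Rises had a median of 0.71, 0.74 and 0.82 on the log2 scale in HY, NST and TN, against median falls of -0.44, -0.39 and -0.37. A rise of more than 2-fold was found for 168 genes in HY, 179 in NST and 153 in TN, and a fall of that size for 20, 19 and 13 genes. Of the rising genes 55, 66 and 49 rose more than 4-fold. Some of them were close to silent without LPS: 58 of the rising genes in HY, 74 in NST and 75 in TN had a mean below 1 CPM (counts scaled to library size) in control males. The median change over all tested genes was -0.0054 in HY, -0.0038 in NST and -0.0086 in TN. The HY control library of male 44 in KF correlated with the HY median at only 0.924, and without it the count in HY was 875 in place of 710.

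The files do not pair the gene identifiers with names, so single genes are given by identifier only. ENSTGUG00000017314 rose in all 3 regions. In HY it stood at 9.74 ± 6.08 CPM in LPS males (SD, n = 22) and 0.214 ± 0.274 in controls (SD, n = 23), a log2 change of 5.62 (SE 0.36, edgeR adjusted p = 1.32e-15). Its log2 change was 4.75 in NST (SE 0.36, adjusted p = 1.26e-13) and 5.77 in TN (SE 0.42, adjusted p = 3.71e-13). The lowest LPS library lay above the highest control library in all 3 regions, at 1.78 against 1.19 CPM in HY, 1.76 against 1.16 in NST and 1.22 against 0.393 in TN. It passed the test in each of the 4 settings in every region.

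ENSTGUG00000005326 also rose in all 3 regions. In NST it reached 43.0 ± 32.8 CPM in LPS males (SD, n = 23) against 1.06 ± 1.49 in controls (SD, n = 23), a log2 change of 5.42 (SE 0.39, edgeR adjusted p = 5.83e-14). In HY its log2 change was 5.07 (SE 0.39, adjusted p = 4.19e-13) and in TN 4.40 (SE 0.40, adjusted p = 1.28e-10). In TN of NF males its log2 change of 3.06 (SE 0.80) did not pass (adjusted p = 0.209).

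The largest mean falls belonged to genes whose level varied widely between control males. ENSTGUG00000008278 averaged 8.01 ± 5.85 CPM in LPS males in HY (SD, n = 22) and 72.9 ± 134.3 in controls (SD, n = 23), whose values ran from 1.58 to 457. Its log2 change was -2.98 in HY (SE 0.67, edgeR adjusted p = 0.00279), -2.81 in NST (SE 0.65, adjusted p = 0.00355) and -2.56 in TN (SE 0.64, adjusted p = 0.0113). ENSTGUG00000017101 changed by -2.30 in HY (SE 0.65, adjusted p = 0.0245), -2.03 in NST (SE 0.64, adjusted p = 0.0496) and -2.82 in TN (SE 0.66, adjusted p = 0.00554). Neither fall passed the test in any single setting of any region, and control and LPS males overlapped in level. For ENSTGUG00000008278 the highest ISO control value was 274, 273 and 295 CPM in HY, NST and TN. The regions came from the same males, and a call in all 3 was the rule by which these genes were chosen. The 3 changes of a gene are therefore not independent results.

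Many of the called genes were shared between the regions. Of the genes tested in both HY and NST, 366 rose in both and 125 fell in both, where independent lists of these sizes would share 17.4 and 4.43. TN and HY shared 297 rises (12.5 for independent lists) and 78 falls (2.81), and TN and NST shared 304 rises (13.99) and 82 falls (3.23). No gene passed the test as a rise in 1 region and as a fall in another. Over the 14140 genes tested in every region, 276 rose and 61 fell in all 3, out of 1129 called in at least 1. The regions came from the same males, so these lists were not independent. With the males of each group parted into 2 sets and the regions taken from different sets, NST and HY still shared 155 and 132 rises in the 2 arrangements, where independent lists would share 3.61 and 3.11. TN and HY then shared 107 and 79 rises (2.23 and 1.71 for independent lists), and TN and NST 105 and 87 (2.43 and 2.12). Across all genes the correlation of NST and HY log2 changes was 0.757 and 0.792 with the same males and 0.537 and 0.472 with different males. For TN and HY it was 0.745 and 0.592 with the same males and 0.454 and 0.292 with different males, and for TN and NST 0.785 and 0.582 against 0.451 and 0.330. Genes are not independent replicates in these values.

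**Figure D2:**
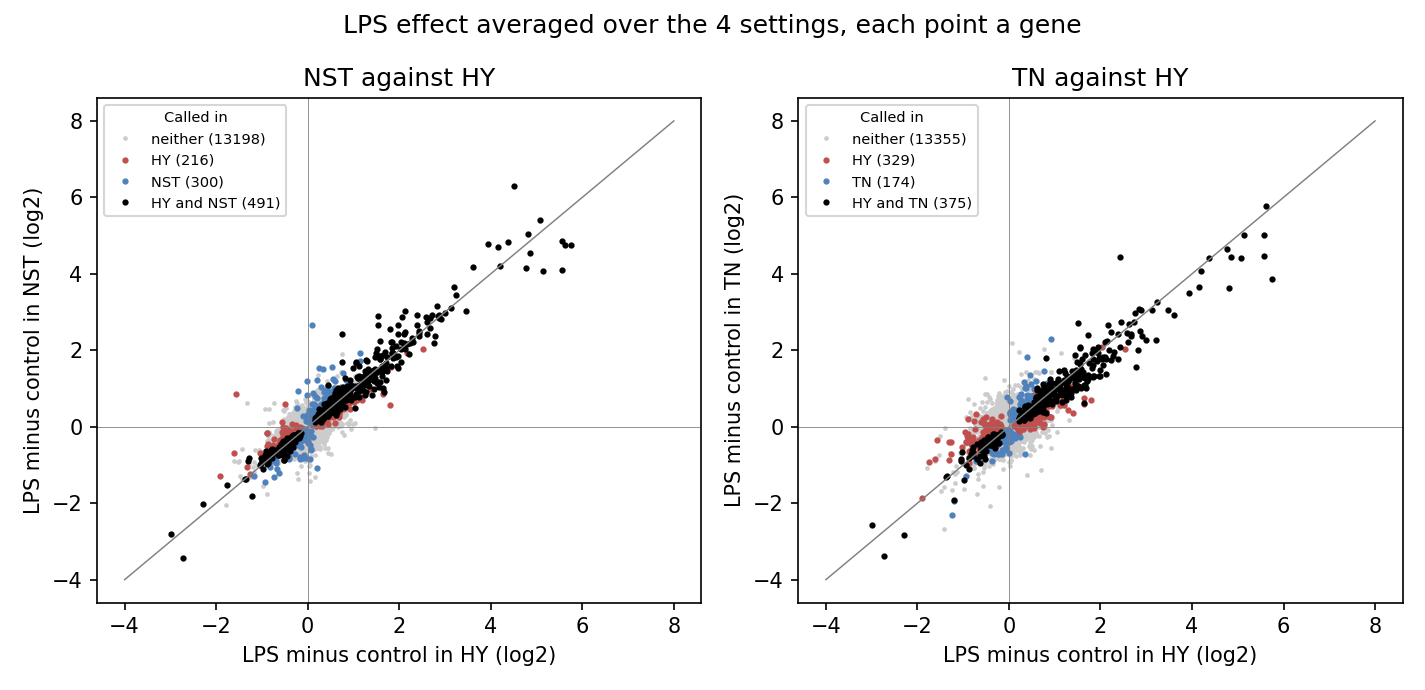
Log2 change from control to LPS averaged over the 4 settings in NST (left) and TN (right) against HY, with 1 point per gene; the colour gives the regions in which the gene passed the test and the line marks equal change. The 366 rises shared by HY and NST and the 297 shared by HY and TN lie along the line.

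The effect of LPS differed between 2 regions for a few genes, tested within males. The response differed for 16 genes between NST and HY, 29 between TN and HY and 23 between TN and NST (edgeR with male as a block). In NST against HY, 10 of the 16 had a higher fitted change in NST, above 0 and larger in size than that in HY. The same held in HY for 18 of the 29 between TN and HY, and in NST for 19 of the 23 between TN and NST. The fitted changes had opposite signs in the 2 regions for 3, 14 and 3 of these genes, in the same order. Between TN and HY, 4 of the 29 passed the averaged LPS test in neither region and 10 in both. The median absolute difference of these genes was 1.02, 0.46 and 0.99 on the log2 scale, in the same order. Without the block for paired regions the counts were 8, 1 and 7, and limma on differences within males called 8, 3 and 24. An unadjusted p under 0.05 was found for 759, 1753 and 1406 genes.

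Each social setting showed a response to LPS in each region. In HY 142 genes rose and 17 fell in ISO, 148 and 39 in KFC, 120 and 44 in KF, and 83 and 8 in NF. In NST 163 rose and 22 fell in ISO, 126 and 19 in KFC, 161 and 28 in KF, and 83 and 11 in NF. In TN 130 rose and 24 fell in ISO, 97 and 23 in KFC, 81 and 16 in KF, and 13 and 2 in NF. NF males thus had the fewest calls in every region, although they also had the fewest libraries in TN. Between settings the lists of rising genes overlapped. ISO and KFC, with 142 and 148 rises in HY, shared 90, with 163 and 126 in NST shared 87, and with 130 and 97 in TN shared 64, where independent lists would share 1.46, 1.43 and 0.864. Of the shorter NF lists, in HY 70 of the 83 rises in NF were also called in ISO, in NST 63 of 83, and in TN 13 of 13, where independent lists would share 0.817, 0.940 and 0.116. No gene passed the test as a rise in 1 setting and as a fall in another within a region. Of the 473 genes that rose in HY on average, 462 had a higher mean after LPS in all 4 settings. The same held for 514 of 530 in NST and 363 of 383 in TN, which is partly built in, since the average is made of the 4 settings. In HY 59 of the rising genes passed the test in all 4 settings, in NST 56 and in TN 12. Single males moved some counts by more than 1.5 times. In HY ISO fell to 103 without LPS male 8, KFC to 93 without LPS male 67, and NF to 48 and 49 without LPS males 59 and 57. In NST ISO fell to 116 without LPS male 56. In TN ISO fell to 84, 87 and 100 without males 52, 8 and 56, KFC to 65, 76 and 77 without males 67, 70 and 66, and KF to 63 without LPS male 41. Without HY44 the count of KF in HY was 127, and without NST3 and NST4 that of NF in NST was 69.

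**Figure D3:**
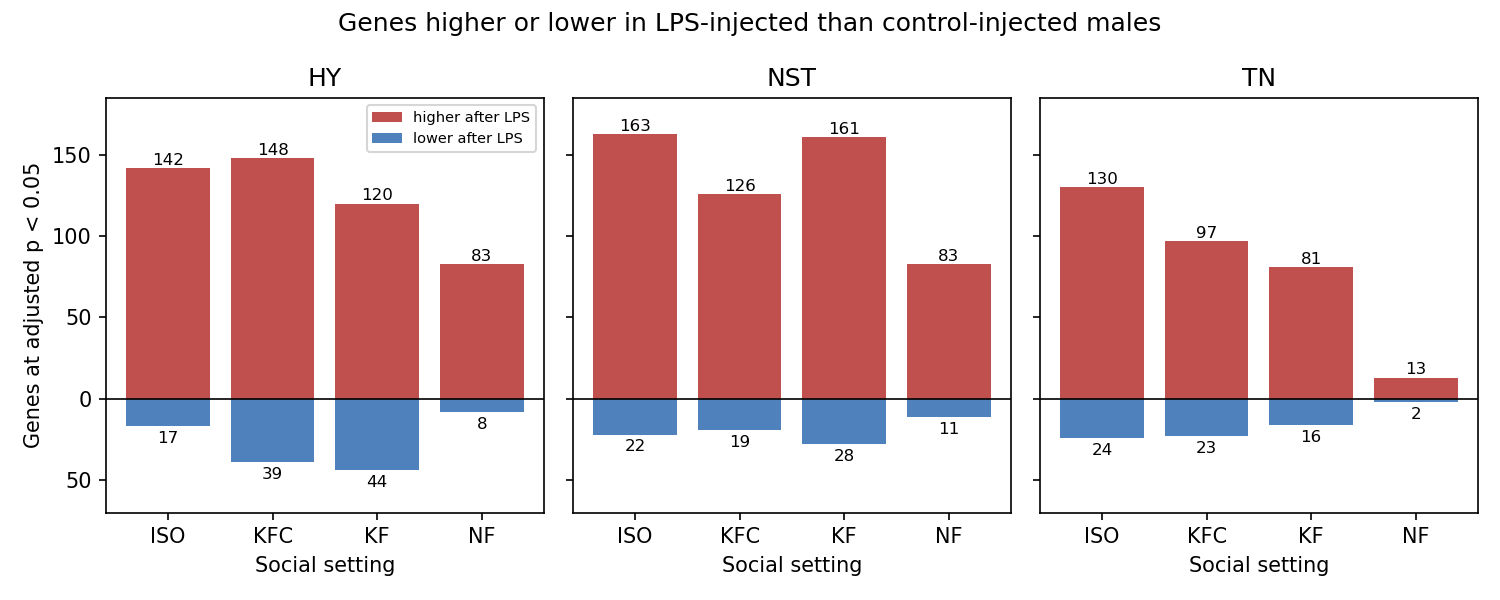
Number of genes at adjusted p under 0.05 that were higher (upward bars) or lower (downward bars) in LPS than in control males, by setting and region. NF has the shortest upward bars, at 83 genes in HY, 83 in NST and 13 in TN.

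Whether the response itself differed between settings was tested directly, and few or no genes passed. The interaction of LPS and setting gave 0 genes in HY, NST and TN with edgeR, with 704, 557 and 691 genes at an unadjusted p under 0.05. DESeq2 gave 0, 6 and 0. Among the 18 comparisons of the response between 2 settings, 1 gene passed in NST between KF and ISO, and the response in NF against the mean of the rest differed for 1 gene in NST. In simulated data in which 200 genes lost the response in NF, the interaction test recovered 52% of changes of 1 on the log2 scale in HY, 58% in NST and 46% in TN, and 8%, 16% and 6% of changes of 0.5. Changes of 2 on the log2 scale were recovered for 80%, 88% and 64%, in the same order. Differences of 2-fold or less were therefore often not detectable at this group size, and some larger ones were missed as well.

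A score was also computed for each library, the mean log2 CPM over the genes called in the region, with genes that fell counted negatively. It is a level, and its rise is the mean of LPS males minus that of control males. In genes chosen from the other 3 settings only, the score rose by 0.83 ± 0.07 (SE, n = 6 and 6) in ISO, 1.04 ± 0.15 (n = 5 and 5) in KFC, 0.61 ± 0.07 (n = 6 and 6) in KF and 0.59 ± 0.08 (n = 5 and 6) in NF in HY. These values rest on different gene sets and are not set against each other. The exact permutation p was 0.00794 in KFC, where the groups allow none smaller, and 0.00216 in the other 3 settings of HY, again the smallest possible. The same p-values were found in NST. In TN they were found in ISO, KFC and KF, while NF rose by 0.38 ± 0.12 (n = 4 and 5, exact permutation p = 0.0317). Over all settings and regions the Benjamini-Hochberg adjusted values were 0.00325, 0.00866 and 0.0317 for p of 0.00216, 0.00794 and 0.0317. Every LPS male lay above every control male of its setting and region except in TN of NF males, where the lowest LPS score was 0.18 and the highest control score 0.24.

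With 1 gene set per region, the score rose in NF by 0.68 ± 0.07 in HY (SE, n = 5 and 6), against 0.74 ± 0.06 in ISO, 0.86 ± 0.11 in KFC and 0.76 ± 0.07 in KF. In NST the rise in NF was 0.64 ± 0.05 (SE, n = 6 and 6), against 0.73 ± 0.07, 0.81 ± 0.10 and 0.79 ± 0.04. In TN it was 0.64 ± 0.10 (SE, n = 4 and 5), against 0.84 ± 0.10, 0.93 ± 0.10 and 0.80 ± 0.08. NF minus the mean of the other settings came to -0.11 ± 0.09 in HY (2-sided permutation p = 0.261), -0.14 ± 0.07 in NST (permutation p = 0.0632) and -0.22 ± 0.11 in TN (permutation p = 0.0987). After Benjamini-Hochberg adjustment over the 3 regions these were 0.261, 0.148 and 0.148. The lower mean in NF did not pass the test in any region. Without male 16, 19, 39, 57, 63, 65 or 71 the permutation p in NST fell under 0.05, the lowest being 0.0273.

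**Figure D4:**
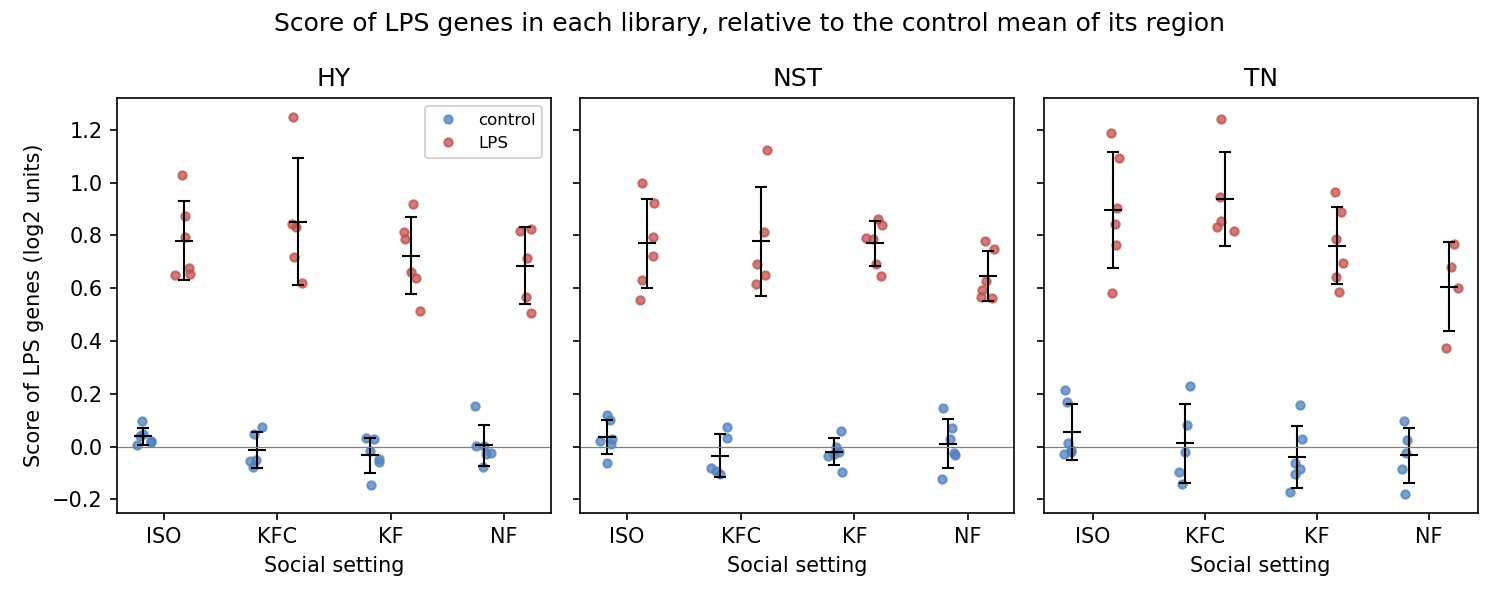
Score of LPS genes per library in log2 units, relative to the control mean of the region, by setting (points are males, bars are mean and SD). LPS males lie above control males in each setting, which is partly built in, since the genes were called for LPS in these same libraries. With genes chosen from the other settings, NF males in TN overlapped (lowest LPS score 0.18, highest control score 0.24). The rise in NF was the smallest in each region, by an amount that did not pass the test.

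The social setting by itself left few detectable marks. Among control-injected males the 4 settings differed for 0 genes in HY, NST and TN with edgeR, with 827, 649 and 725 genes at an unadjusted p under 0.05. In NST 13 genes passed without control NF male 58 and 3 without LPS ISO male 16, and in TN 2, 1 and 1 without control KFC males 70, 62 and 68. Averaged over both injections, the 4 settings differed for 6 genes in NST and 0 in HY and TN with edgeR (1728, 606 and 1308 at an unadjusted p under 0.05). Between single settings, 68 genes differed between KFC and KF in NST, 64 of them higher in KFC, and the other 17 comparisons of 2 settings gave at most 3 genes. The 68 genes rested on single libraries: without the control KFC replicate 62 none passed, and without the control KF replicates 31 or 34 only 6 or 7 did. It was 30 to 45 without male 30, 32, 33, 35, 36, 44, 64, 67, 69, 70 or 71, 107 without male 5 and 117 without male 48. DESeq2 called 135. The KFC males carry the numbers 62 to 71 and all others lie between 3 and 59, so the numbering is not shared between KFC and the other settings. In simulated data a change of 1 on the log2 scale in control KFC males was recovered for 74% of genes in HY, 68% in NST and 66% in TN.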

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

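The tests of the number of libraries in NF, of the score of LPS genes, of library HY44, of the exchange of 2 hypothalamic libraries, and of other splits for the interaction and for setting were chosen after the pattern was seen; the tests of the spread between NF males and of chance similarity between males were set out before their values were known.

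NF males had the fewest genes called for LPS in all 3 regions: 91 in HY, 94 in NST and 15 in TN. The regions share most of these males, so the 3 counts are not independent. A larger spread between NF males was tested by the mean variance within groups over the LPS genes, which was 0.938 times that of the other settings in HY, 1.01 times in NST and 0.991 times in TN, against this explanation. The number of libraries in NF does not account for the pattern in NST, where ISO and KF have as many libraries and at least 1.97 times as many calls. Nor does it in TN, where the other settings reduced to the smaller NF sizes still had a median of at least 3.67 times as many over 20 draws. In HY the ratios were 2.07 for KFC, which has fewer libraries than NF, 1.59 for ISO and 1.36 for KF, of which the first goes against the number of libraries, but that number cannot be told apart from a weaker response there, because draws of ISO and KF reached down to 1.13 and 1.18 times the NF count and KFC fell from 187 to 93 without LPS male 67. A weaker response of the same genes in NF males may contribute, but the lowest permutation p of the score over the regions was 0.0632 and the interaction gave 0 genes in each region with edgeR (704, 557 and 691 at an unadjusted p under 0.05 in HY, NST and TN) and 0, 6 and 0 with DESeq2, so this remains a hypothesis; other tests of NF that were tried were the comparison with the mean of the rest (1 gene in NST), a median score, a score from genes of the other regions, and 18 held-out pairs of settings (lowest exact p = 0.0364, adjusted 0.656).

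The HY libraries of males 32 and 33, both LPS males in KF, went with each other's NST and TN libraries. Over 200 genes whose level went together between NST and TN in males other than 19, 32 and 33, HY32 correlated at 0.944 with NST33 and TN33 and at -0.223 and -0.229 with NST32 and TN32, and HY33 at 0.944 and 0.924 with NST32 and TN32 and at -0.283 and -0.234 with NST33 and TN33. The lowest of the 4, 0.924, is within the range of males with themselves when 19, 32 and 33 are left out (121 pairs, lowest 0.862), and 0% of 544 pairs of different males of a group, with the same males left out, reached it (highest 0.507). An exchange of the 2 HY libraries, or equally of both other regions, is the candidate explanation; no biological explanation was tested. The males share a group, so tests within a region are unaffected, and with the 2 libraries exchanged the block fit called 17, 31 and 25 genes for the difference of the LPS effect between NST and HY, TN and HY, and TN and NST (16, 29 and 23 as labelled).

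NST of male 19 matched its own number at only 0.252 in HY and 0.255 in TN over the same 200 genes, and best matched male 64, at 0.494 and 0.497. The lowest r of other males with themselves was 0.862, and the highest of different males of a group 0.507. No male was therefore found to which this library belongs. Its labels, NF and LPS of male 19, were used as given, also in the block. Without it NF in NST had 89 genes in place of 94. The score difference of NF in NST then had a permutation p of 0.0477 in place of 0.0632.

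HY44, a control male in KF, had a correlation of 0.924 with the HY median, against 0.975 to 0.982 in the rest of its group, stood far from the others, and had 1420 genes at under 50% of the lowest other HY library, where no other library had more than 28. Tissue from NST or TN in the dissection was tested by the correlation across genes of its deviation with the differences between regions. It was at most 0.0589, which argues against such tissue as the main source of the deviation. HY44 lay 0.168 of the way to NST and 0.165 of the way to TN. A smaller share of such tissue is not excluded, since the many lowered genes can themselves reduce this correlation. Its 10 most abundant genes took 20.5% of the counts, only 7.14 percentage points above the median of the other libraries, too little to lower so many genes by that much. What remains open, such as the state of its RNA, was not tested. Without it the averaged LPS effect in HY called 875 genes in place of 710, and KF in HY 127 in place of 164.

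Other libraries far from their group, out of 72 sets of values examined, where chance alone picks about 1 in 20 and 7 were picked, were these. The total count of HY31 was 13159800 against 7842360 to 9708330 in its group. The correlation with the HY median was 0.967 for HY58, 0.968 for HY8 and 0.965 for HY67, against at least 0.975 in the rest of each group, and the correlation with the TN median was 0.977 for TN53 against 0.979 to 0.980. The score of LPS genes was 0.15 in the control library HY28, against -0.079 to 0.0033 in the other control NF males, and the NST library of that male also had the highest score among the control NF libraries of NST, 0.15. HY28 and NST28 were the most highly correlated of all pairs of libraries (r = 0.983), and their deviations lay 0.430 of the way from HY to NST and 0.355 of the way from NST to HY. Larger shifts were found for 2 NF libraries, NST3 at 0.556 of the way to HY (r = 0.364 across genes, other NST libraries at most 0.325) and NST4 at 0.663 of the way to TN (r = 0.432, others at most 0.296), and without both NF in NST had 69 genes in place of 94.

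The effect of LPS differed between regions for 16 genes (NST and HY), 29 genes (TN and HY) and 23 genes (TN and NST), and in NST between KF and ISO for 1 gene and between NF and the mean of the rest for 1 gene. They are given because the difference itself passed its test. Between settings, adjustment was made within each comparison only. A gene passed in 1 of 18 comparisons of 2 settings and in 1 of 3 of NF with the rest, which chance could also give.

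Chance was examined by counting genes in 80 splits of the same libraries. For the averaged LPS effect only the real split, 1 of 80, gave as many genes in each region. It called 710, 801 and 555 genes in HY, NST and TN, against at most 181, 1 and 2 in other splits. The smallest share that 80 splits can give is 1 of 80. The other splits exchanged LPS and control males in all 4 settings at once. The LPS effect thus entered their spread within groups, which can lower their counts. For single settings the real split alone gave as many genes, again 1 of 80, in ISO, KF and NF of every region. Other splits called at most 1, 6 and 1 genes in HY, NST and TN in ISO, 28, 1 and 3 in KF, and 20, 18 and 1 in NF. In KFC the real split was alone in HY and TN (at most 1 and 1 elsewhere). In KFC of NST 2 of 80 splits, the real one included, gave as many, and the other gave 275 genes against 145. For the interaction and for setting in control males the real split gave 0 genes with edgeR, a count that all 80 of 80 splits reach by construction, so the splits decide nothing there. Other splits reached 1, 1 and 196 genes for the interaction and 5, 10 and 268 for setting in HY, NST and TN. Counts as high as 196 and 268 beside a real count of 0 may point to a structure of the TN libraries, which was not tested. High counts in other splits were not particular to TN, with 275 in KFC of NST and 181 for the averaged effect in HY. For KFC against KF over both injections in NST 1 of 80 gave 68 genes, with at most 4 elsewhere. That comparison was the highest of 18 and was added after the data were seen, whereas the splits count it alone. They therefore do not measure chance for the highest of 18. For differences between regions, with limma within males, 1 of 80 gave the real counts of 8, 3 and 24 genes for the LPS effect (at most 1, 0 and 0 elsewhere) and 6633, 8682 and 6126 genes for control males (at most 0, 2631 and 1 elsewhere).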

How the results depend on the processing

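The limma tests, the score, KFC against KF over both injections and the fits without HY44, NST3 and NST4 or with HY32 and HY33 exchanged were added after the data were seen. Of 1130 alternative values for 37 results, 1061 stayed within 1.5 times the count or on the same side of the threshold. Many of these were counts of 0 that stayed at 0. Only the score difference of NF has a direction, and it did not turn in any region. The averaged LPS counts stayed between 658 and 875 in HY, 711 and 949 in NST, and 466 and 683 in TN, left-out libraries included. NF had the fewest calls of the 4 settings in 16 of 17 combinations of region and alternative, the exception being NST fitted to only the groups compared. These combinations refit mostly the same libraries, and the regions share most males, so they are not independent of each other.

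Fitted to only the groups compared, which use fewer libraries, counts fell in HY to 91 (KFC), 68 (KF) and 37 (NF), in NST to 116 (ISO), 48 (KFC) and 62 (NF), and in TN to 98 (ISO), 48 (KFC) and 56 (KF). The setting effect in NST was then 1. DESeq2 called more: 251 in KF of HY, 222 in KFC of NST, 6 for the interaction in NST, 135 for KFC against KF in NST, and 264 (ISO), 199 (KFC) and 30 (NF) in TN. With 2 surrogate variables NF in TN had 23. Without the filter on low counts the setting effect in HY was 1 and the LPS difference of TN and HY 14. The cause of these changes was not tested.

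The block for paired regions mattered for the LPS difference: without it 8 genes passed for NST and HY, 1 for TN and HY and 7 for TN and NST, and limma within males gave 8 and 3 for the first pairs, the first 13 with HY32 and HY33 exchanged. For region differences in control males the counts without the block were 5115, 7669 and 4280. Leaving out libraries in turn was not run for the fit with the block, but was for limma, which gave 2 to 5 genes for TN and HY (5 without male 33, 39 or 47).

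Without each library in turn, counts ranged in HY from 103 (without LPS male 8) to 182 in ISO, 93 (without LPS male 67) to 198 in KFC and 48 to 103 in NF (48 and 49 without LPS males 59 and 57). In NST ISO ranged from 116 (without LPS male 56) to 232, and the setting effect from 0 to 13 (13 without control NF male 58 and 3 without LPS ISO male 16). In TN ISO ranged from 84 to 195 (84, 87 and 100 without males 52, 8 and 56), KFC from 65 to 173 (65, 76 and 77 without males 67, 70 and 66), KF from 63 (without male 41) to 111, and the setting effect from 0 to 2 (2 without male 70, 1 without male 62 or 68). KFC against KF in NST ranged from 0 to 117. It was 0 without male 62, 6 without 31, 7 without 34, 30 to 45 without male 30, 32, 33, 35, 36, 44, 64, 67, 69, 70 or 71, 107 without 5 and 117 without 48. The score difference of NF in NST ranged from -0.17 to -0.11, with permutation p from 0.0273 to 0.136, and passed 0.05 without male 16, 19, 39, 57, 63, 65 or 71. The planned gene-list tests and list scores were not run, since no identifier matched the table of zebra finch genes that was used.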

Other observations

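Both explanations below were set out before the correlations were computed.

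The level of the LPS genes in a male was correlated between regions. The score over the 337 genes called in all 3 regions, centred within each group, was compared between regions among LPS males and among control males, 6 comparisons in all. Among LPS males Pearson's r was 0.77 between NST and HY (22 males, permutation p = 4e-05, Spearman's rho 0.66, permutation p = 0.00087), 0.84 between TN and HY (20 males, permutation p = 3e-05, rho 0.75, permutation p = 0.00032) and 0.68 between TN and NST (21 males, permutation p = 0.00047, rho 0.52, permutation p = 0.0172). Among control males r was 0.73 (23 males, permutation p = 0.00012, rho 0.66, permutation p = 0.00068), 0.73 (22 males, permutation p = 0.00017, rho 0.62, permutation p = 0.00256) and 0.83 (22 males, rho 0.75, permutation p = 0.00017), in the same order. The last r had a permutation p of 1e-05, the smallest that 100000 permutations can give. The Benjamini-Hochberg adjusted p of r was at most 0.00047. Without the 2 males farthest from the median, r was 0.56, 0.75 and 0.50 among LPS males and 0.72, 0.60 and 0.80 among control males. Deviations from group means over all genes also went together between regions of a male, with a median r across genes of 0.539, 0.479 and 0.509, in the same order. No score of other genes was compared, so the correlation is not shown to be particular to the LPS genes.

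One hypothesis is that males differ in the strength of the response in all regions, for which the lowest r was 0.683 among LPS males. The other is a background of each male that is not a response to LPS, for which the lowest r was 0.731 among control males. Since the genes also went together in males that received no LPS, the 2 cannot be told apart from these correlations. The first condition set beforehand, a permutation p under 0.05 in all 3 pairs of LPS males, was met. The conditions set beforehand for the second were that r among control males be as high as among LPS males in every pair, which failed for NST with HY and TN with HY, or, against it, lower by over 0.3 in every pair, which was not met either. For the first explanation, the further condition that r exceed that of control males by 0.3 was added once the control values were seen. HY32 and HY33 enter as labelled.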
